A study of Mus musculus with 8 samples.

How the data were processed

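Total RNA of mouse bone marrow mesenchymal stem cells (MSCs), of cells differentiated from them and of reprogrammed cells was extracted with Qiagen RNeasy, and biotin-labelled cRNA for Illumina arrays was amplified with an Ambion MessageAmp kit, per the labels' protocols. There were 8 arrays, 2 of undifferentiated MSCs and 1 each of 6 other cell types. Groups were taken from the labels' cell types. Nothing in the labels says that arrays came from separate cultures or animals, so p-values measure only the spread between these arrays. Here that is a spread between lineages and between the 2 MSC arrays.

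The values analysed were the authors' deposited log2 values of 45281 probes. The software, background correction and normalization behind them are not given in the sources used here. The scale was read from the values: each column had a median of 3.901 after rounding and a maximum of 15.05, and the sorted columns differed by at most 0.0175 above a log2 value of 2, as quantile normalization between arrays leaves them. Below 2 they differed by up to 1.10, and values ended at a floor of 0. A second table, of signals and detection p-values before normalization, had 16 value columns whose names match no sample label, and none was used. The design set before the data were examined started from that table, with a background correction on negative controls and a filter on detection p. The deposited log2 values and a filter on level took their place. The level of 6, the offset of 16 and the split into array sets described here were chosen after the values had been seen.

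Gene symbols came from the platform annotation of the probes, in which 34885 probes had 1 symbol, 18 had several and 10378 had none, so that these 10378 are unnamed here. The Entrez identifiers of 34807 probes were matched to the RefSeq gene table of assembly GRCm38.p6, and its symbols were used for them. Deposited values x were transformed to log2(2^x + 16), which damps differences among dim probes and understates changes of dim genes. State tests used genes whose probe reached a deposited log2 value of 6 on at least 2 of 8 arrays. This kept 14082 probes (31.1%), 12358 of them named, and 8317 genes, each represented by its probe of highest mean. Of these genes, 2910 had several probes that passed this filter. Comparisons of single arrays used 9069 genes at that level on at least 1 array, a choice made after counts at 2 arrays had been seen, because genes of a single lineage drop out at 2. A gene under 6 on every array of the dimmer side has only a bound there. For it "at least N-fold" sets the brighter side's mean against the higher of the dim value and 6.32, the level of 6 after the offset, so that a bound against MSCs as the brighter side holds against the mean of both arrays, and list medians are also given with such genes at their bound.

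Differences between the 3 states (MSC, differentiated, reprogrammed) were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) over all 8 arrays, two-sided, with Benjamini-Hochberg adjustment at 0.05. Every adjusted p of a gene is limma's. Lineages stood as the replication of a state. A set of 26 gene lists, also fixed by then, was tested with camera at a preset correlation of 0.01, over the 23 lists with at least 3 genes tested. Camera with an estimated correlation and fry were the alternatives. Fry tests whether a list's genes move on balance in 1 direction and compares them with no other genes. A cell type with 1 array has no spread of its own. Its genes were counted by size, at a log2 difference of at least 1 (against both MSC arrays where MSCs were the other side), and a list's median was placed by its percentile among 10000 random lists of the same size matched on mean level. Named genes followed a rule of the same design. It takes, per state contrast and direction, the 10 largest differences that passed the test without overlap of arrays, filled where fewer passed by genes at an unadjusted p under 0.05. It adds the 5 largest per direction of each single-array comparison, the 4 largest members of each list and 24 marker genes. Other named genes were chosen after their values were seen.

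Arrays with a d number in the title (MSC d0 and the differentiated cells) had 4317 to 5204 probes at 0, and those with a p number (MSC p4 and the reprogrammed cells) had 6815 to 7652. These groups of 4 arrays are called array sets here. Reprogrammed and differentiated cells lie in different sets and are joined only through 1 MSC array in each, so values with the array set as a block are given beside the results. For comparisons with MSCs the blocked value is the value within 1 set.

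The state test was tried on simulated data. With 200 of 8317 genes changed between reprogrammed and differentiated arrays, it recovered 6 of 67 genes changed by a log2 of 1, 49 of 67 changed by 2 and 65 of 66 changed by 4, with 7 false among 127 calls. A simulated lowering of 1 list gave that list an adjusted p of 4.16e-20 and called 0 of the other lists. Simulated genes were drawn independently of each other, with no array set or lineage. On the arrays the estimated correlation of cell cycle genes was 0.79 between reprogrammed and differentiated cells. The simulation therefore does not show how often lists are called falsely, or how many changed genes are found, in these data. Alternatives covered the offset, the level filter, the probe choice, each array left out, the model, the lineage or the array set as a block, and the list test. The number of arrays limits the precision. Near-identical or close family members can share signal, and their values are uncertain. These are the Prl2c genes, Mt1 and Mt2, Bglap and Bglap2, Aldh1a1 and Aldh1a7, Lyz1 and Lyz2, Amy2a5, histone genes and the pseudogene Sms-ps. Runx2, Spp1, Ly6a and Mki67 had no probe named here and were not analysed here.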

Results

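Gene expression was measured on 8 Illumina arrays of bone marrow mesenchymal stem cells (MSCs) of C57BL/6J mice and cells made from them. MSCs are stromal cells of the marrow that can form fat, cartilage and bone. Undifferentiated MSCs had 2 arrays, titled d0 and p4. Differentiated adipocytes (titled d7), chondrocytes (d28) and osteocytes (d21) had 1 array each, as had reprogrammed osteocytes, adipocytes and chondrocytes (each titled p1). The meaning of d and p is not given in the labels. Each column of deposited log2 values had a median of 3.901 after rounding, and 12610 of 45281 probes reached a log2 value of 6 on each array. The series addressed the reprogramming of cells committed to a lineage.

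Across 8317 genes, each reprogrammed array lay closer to MSC p4 than any differentiated array did. The array of MSC p4 correlated at r = 0.983 with reprogrammed adipocytes, 0.981 with reprogrammed chondrocytes and 0.943 with reprogrammed osteocytes, and at 0.792, 0.867 and 0.851 with differentiated adipocytes, chondrocytes and osteocytes. The array of MSC d0 correlated at 0.892, 0.951 and 0.955 with the reprogrammed adipocytes, chondrocytes and osteocytes, and at 0.817, 0.888 and 0.930 with the differentiated ones, so that differentiated osteocytes lay closer to MSC d0 than reprogrammed adipocytes did. Both MSC arrays correlated at 0.914 with each other. These correlations run across genes, which are not independent replicates. The differentiated adipocytes stood farthest out on the first principal component, at 76.1, with the reprogrammed arrays between -40.3 and -21.9. MSC p4 lay within that range, at -33.9, and MSC d0 outside it, at -1.26. MSC p4 is also the MSC array in the array set of the reprogrammed arrays, so closeness to it does not measure the state alone.

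**Figure D1:**
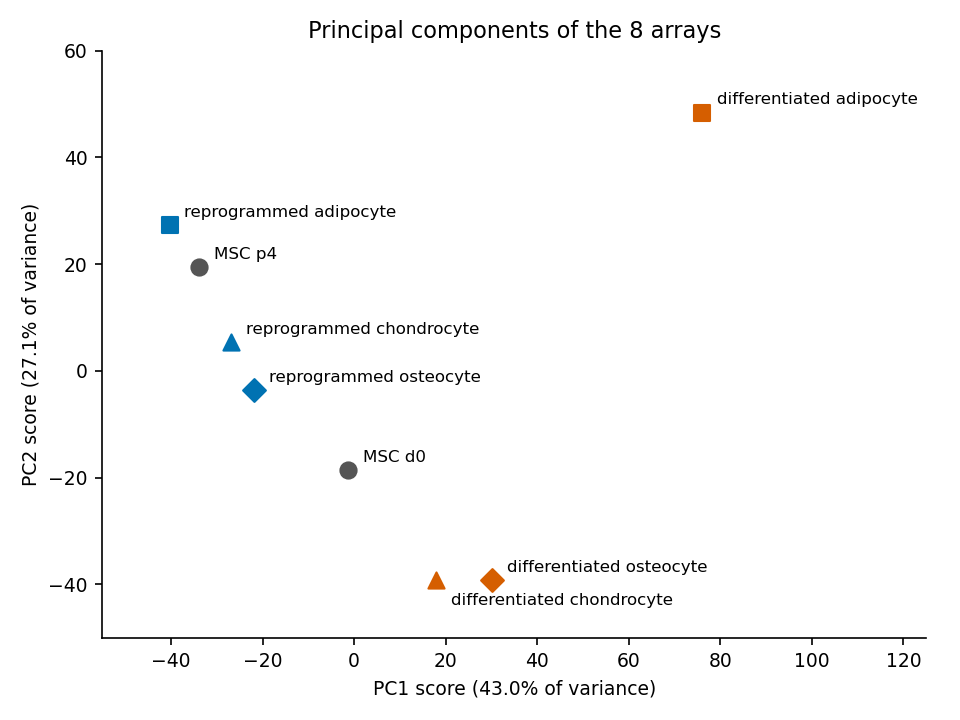
Principal components 1 (43.0% of the variance, horizontal) and 2 (27.1%, vertical) of log2 expression over 8317 genes, 1 symbol per array: grey MSC, orange differentiated, blue reprogrammed; circle no lineage, square adipocyte, triangle chondrocyte, diamond osteocyte. The reprogrammed arrays lie at -40.3 to -21.9 on component 1, near MSC p4 at -33.9, and the differentiated adipocytes at 76.1. MSC d0 lies outside the reprogrammed range, at -1.26. MSC p4 shares an array set with the reprogrammed arrays.

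The MSC arrays give the background difference between arrays of 1 cell type label, and it was wide. By the size rule 560 genes were higher and 688 lower on MSC p4 than on MSC d0. Interferon response genes had a median log2 difference of -2.95 (-2.44 with dim genes at their bound), and 24 of 25 were at least 2-fold lower on MSC p4. Among them Ifit3, an interferon-induced antiviral gene, differed by -5.45, and Ifi27l2a was at least 25.5-fold lower. Cell cycle genes were higher on MSC p4, with a median of 1.56 over 37 genes, 32 of them at least 2-fold. The placental prolactin-family genes Prl2c2, Prl2c4 and Prl2c3 differed by 6.08, 5.70 and 5.58, with family members that can share signal. Scara5, Dcn (decorin, a matrix proteoglycan) and Inmt were lower by at least 20.4-fold, 20.7-fold and 20.2-fold. Serpinb9g was at least 7.78-fold higher. No test applies to 1 array against 1.

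Differentiated cells, compared with MSCs to find what the 3 lineages shared, carried more Fkbp5, Serpina3n, Vldlr, Mertk and Tns1. Fkbp5, a co-chaperone of the glucocorticoid receptor and a standard target of it, was higher by a log2 of 4.33 (SE 0.28, adjusted p = 0.0033; 3 differentiated against 2 MSC arrays). Serpina3n, a secreted protease inhibitor, was higher by 7.05 (SE 0.54, adjusted p = 0.00539) and at least 28.6-fold. Vldlr, the very low density lipoprotein receptor, rose by 4.12 (SE 0.41, adjusted p = 0.026), the receptor tyrosine kinase Mertk by 3.32 (SE 0.39, adjusted p = 0.0458; at least 7.21-fold) and the focal adhesion gene Tns1 by 2.78 (SE 0.32, adjusted p = 0.0458; at least 3.35-fold). These were the 5 genes that passed limma's test, all higher, against 385 higher and 477 lower at an unadjusted p under 0.05. With the array set as a block Fkbp5 alone of the 5 passed, at 4.57 (adjusted p = 0.0386). The calls were lost for Serpina3n (7.02, adjusted p = 0.0893), Vldlr (3.41, adjusted p = 0.0893), Mertk (2.99, adjusted p = 0.43) and Tns1 (3.04, adjusted p = 0.258).

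Other genes had differences of similar size without passing. Aldh1a7 differed by 6.01 (adjusted p = 0.0523; at least 30.3-fold), Hsd11b1, which regenerates active glucocorticoid, by 4.90 (adjusted p = 0.0959), Sult1a1 by 5.57 (adjusted p = 0.26), Lcn2 by 5.35 (adjusted p = 0.432; at least 12.6-fold) and Adipoq by 4.18 (adjusted p = 0.476). On the lower side stood Esm1 at -3.67 (adjusted p = 0.0965), the chemokine Ccl2 at -3.32 (adjusted p = 0.0924), Egr3 at -3.06 (adjusted p = 0.0588), Pclaf at -3.37 (adjusted p = 0.276), Selp at -3.18 (adjusted p = 0.241) and Sprr1a at -2.87 (adjusted p = 0.144; at least 3.11-fold). Cemip at -2.90, Lockd at -2.87 (at least 2.20-fold), Top2a at -2.86 and Cenpa at -2.78 had adjusted p between 0.283 and 0.432. The cyclin-dependent kinase inhibitor Cdkn1a differed by 1.10 (adjusted p = 0.287).

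Among the gene lists, glucocorticoid target genes rose in differentiated cells, 15 of 18 being higher, with a median log2 difference of 1.14 (0.92 at the bound; camera, adjusted p = 3.36e-10). The list had an adjusted p = 0.128 with an estimated correlation, an adjusted p of 0.0133 with fry, and a median of 1.12 with the array set as a block. Fkbp5 passed over all genes, and 9 passed adjusted over the list alone; Tsc22d3 differed by 3.29 (adjusted p = 0.0523) and Glul by 3.14 (adjusted p = 0.276; at least 4.43-fold). Cell cycle genes fell, 36 of 37 being lower, with a median of -1.78 (-1.62 at the bound; adjusted p = 1.69e-17, and adjusted p = 0.654 with an estimated correlation; blocked -0.96). The mitotic genes Bub1b and Kif11 both stood at -2.75 (Kif11 at least 3.07-fold lower), and 0 members passed over all genes and 19 adjusted over the list alone. Smooth muscle and contractile genes fell as a list, 13 of 13 being lower, with a median of -1.22 (adjusted p = 3.06e-06, and adjusted p = 0.654 with an estimated correlation; blocked -1.16), among them Ankrd1 at -2.99, Tpm2 at -2.69, Acta2 (smooth muscle actin) at -2.36 and Myl9 at -2.35. None of them passed singly, over all genes or adjusted over the list alone.

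Adipocyte markers rose by a median of 1.36 (1.07 at the bound; 18 of 20 higher, adjusted p = 0.00775, and adjusted p = 0.998 with an estimated correlation; blocked 1.59), with Cidec at 3.996 (at least 6.13-fold), Pnpla2 at 2.57 and Dgat2 at 2.39. Fibrillar collagen and matrix genes fell by a median of -0.77 (22 of 25 lower, adjusted p = 0.00783, and adjusted p = 0.998 with an estimated correlation; blocked -0.93), with Timp1 at -1.86, Fbln1 at -1.74, Thbs1 at -1.65 and Fstl1 at -1.51. Without the differentiated adipocyte array their medians were 0.10 (adjusted p = 0.406) and 0.0012 (adjusted p = 0.991), and without the MSC d0 array 0.83 (adjusted p = 0.171) and -0.69 (adjusted p = 0.285). Interferon response genes had a median of -0.77 (22 of 24 lower, adjusted p = 0.0367, and adjusted p = 0.998 with an estimated correlation), with Isg15 at -2.68, Oasl2 at -2.34 and Ifit3 at -2.11. Their median was -2.21 with the array set as a block, 0.69 (adjusted p = 0.203) without MSC d0, -0.48 (adjusted p = 0.262) without differentiated adipocytes and -0.40 (adjusted p = 0.37) without differentiated chondrocytes.

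Inflammatory cytokine and NF-kB target genes had a median of -1.60 but a mean of -0.64 (7 of 9 lower, adjusted p = 0.0285, and adjusted p = 0.446 with an estimated correlation; blocked -1.48). Ccl7 stood at -2.35 (adjusted p = 0.105) and Csf1 at -1.96, and 2 members were higher and 4 lower adjusted over the list alone. The call was lost without MSC d0 (-1.32, adjusted p = 0.0549), differentiated adipocytes (-1.30, adjusted p = 0.0832) or differentiated chondrocytes (-1.35, adjusted p = 0.155). DNA and histone methylation enzymes had a median of -0.36 (10 of 13 lower, adjusted p = 0.0324, and adjusted p = 0.949 with an estimated correlation; blocked -0.19, adjusted p = 0.25), with Uhrf1 at -2.43, Ezh2 at -1.26 and Dnmt1 at -1.25. That call was lost without MSC p4 (-0.19, adjusted p = 0.25) or without the differentiated adipocyte (-0.42, adjusted p = 0.132), chondrocyte (-0.44, adjusted p = 0.0658) or osteocyte array (-0.33, adjusted p = 0.0545). Except for glucocorticoid and inflammatory targets, no member of a called list passed adjusted over the list alone outside the cell cycle.

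The other 15 lists did not pass. Axin2, a target of Wnt signalling, stood at 3.10 (adjusted p = 0.0959; at least 2.51-fold) and the TGF-beta target Tgfbi at -3.34 in a list of median 0.08 (adjusted p = 0.862). Igfbp5 stood at 3.94 (at least 4.43-fold) and the nuclear lamina gene Lmnb1 at -2.18 among CDK inhibitors and senescence genes (median 0.34, adjusted p = 0.583). Medians were -0.13 for MSC surface and stromal markers, -0.53 for mesenchymal transition regulators, 0.18 for macrophage and monocyte markers, -0.14 for osteoclast markers, 0.16 for mitochondrial respiratory chain genes, 0.06 for hypoxia and glycolysis genes, 0.13 for heat shock, ER stress and immediate early genes and -0.13 for cytosolic ribosomal protein genes, with adjusted p between 0.126 and 0.944. Median, mean and test differed in sign for osteoblast and osteocyte markers (median -0.46, mean 0.07), chondrocyte markers (median -0.36, test upward), cholesterol synthesis genes (median -0.06, mean 0.10), pluripotency genes (median -0.17, test upward) and imprinted growth genes (median 0.23, test downward). Some of these lists were tested on few members: 5 of 25 pluripotency genes, 7 of 35 chondrocyte, 3 of 26 macrophage and 3 of 12 osteoclast markers with a probe. With the array set as a block the hypoxia list passed at 0.50 (adjusted p = 0.0139) and the mitochondrial list at 0.20 (adjusted p = 0.0139), and both had an adjusted p = 0.809 with an estimated correlation and that block.

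The count of 5 genes was 56 (47 higher, 9 lower) without differentiated adipocytes, 2 without MSC d0, 1 without MSC p4 and 2 without any 1 of the reprogrammed osteocyte, adipocyte and chondrocyte arrays. Fkbp5 was the gene called in each of these fits. It was 1 with the array set as a block (313 unadjusted) and 0 by limma on the MSC and differentiated arrays alone (509 unadjusted).

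Within single lineages, differentiated adipocytes moved farthest from both MSC arrays, with 841 genes at least 2-fold higher and 907 lower (2754 in all against MSC p4 alone). Adipoq, which encodes the fat cell hormone adiponectin, was 124.7-fold higher, and the lipid droplet gene Cidec was at least 189.9-fold, Lcn2 at least 373.9-fold, Ces1d at least 183.3-fold and Gsta3 at least 107.0-fold higher. Adipocyte markers had a median log2 difference of 3.27 (2.35 at the bound), at percentile 100 of random lists, with 21 of 26 at least 2-fold higher. Of 35 with a probe 25 reached the level of 6 on this array, against 13 to 19 on the others, so the choice by level can raise this median. Deposited log2 values of Pparg, the master regulator of fat cell formation, were 12.3 on this array and 10.3 and 11.1 on the MSC arrays, of Cebpa 9.38 against 5.96 and 6.00, and of Fabp4 6.84 against 3.005 and 3.055. Emp1 (-5.15), the metalloproteinase inhibitor Timp1 (-4.75) and Acta2 (-4.61) were lower, as were Cemip by at least 7.41-fold and Gpr176 by at least 14.2-fold against the mean of the MSC arrays. Cell cycle genes had a median of -2.88, matrix genes -2.45 and contractile genes -2.00, each at percentile 0, and glucocorticoid targets 1.23.

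Differentiated chondrocytes had 612 genes higher and 274 lower (1429 in all against MSC d0 alone and 1991 against MSC p4 alone). C1qtnf3, a secreted protein, was at least 46.7-fold higher, the osteocalcin gene Bglap2 at least 62.9-fold, Igfbp5 at least 29.1-fold, Ptgis at least 34.7-fold and Serpina3n at least 21.05-fold. Itih2 (-4.37), Thbd (-4.28), Esm1 (-3.99) and Egr3 (-3.64) were lower, and Osr2 by at least 6.49-fold against the MSC mean and 3.26-fold against the nearer MSC array. Chondrocyte markers had a median of 1.62 (1.17 at the bound; percentile 99.96), with 12 of 14 at least 2-fold higher. Osteoblast and osteocyte markers had a median of 1.31 (percentile 100), with 13 of 21 at least 2-fold higher. Of 35 chondrocyte and 31 osteoblast markers with a probe, 13 and 20 reached the level of 6 on this array. On the others 5 to 7 and 10 to 15 did. Members that entered through this array can raise both medians. On this array deposited log2 values were 12.6 for Sp7, the bone transcription factor osterix, 10.6 for alkaline phosphatase (Alpl), 10.98 for osteocalcin (Bglap), 9.77 for Col2a1 and 10.7 for Sox9, the regulator of cartilage formation. On MSC d0 and MSC p4 they were 9.16 and 9.16 for Sp7, 5.33 and 6.15 for Alpl, 3.56 and 3.60 for Bglap, 7.38 and 9.08 for Col2a1 and 10.6 and 8.41 for Sox9. Col2a1 was higher still on the reprogrammed osteocytes, adipocytes and chondrocytes, at 9.91, 10.7 and 10.5, so its level does not mark the chondrocyte array. Matrix genes had a median of 0.71, BMP, TGF-beta and Wnt targets 1.14, cell cycle genes -1.20 and glucocorticoid targets 1.16. Beside these groups, 9 of 26 macrophage and monocyte markers reached a log2 value of 6 on this array, against 1 to 3 on the others, and osteoclast markers had a median of 1.26 over 3 genes.

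Differentiated osteocytes had 394 genes higher and 219 lower (1966 in all against MSC p4 alone). Serpina3n was at least 65.9-fold, the aldehyde dehydrogenases Aldh1a7 and Aldh1a1 at least 78.0-fold and 36.1-fold, Cldn11 at least 40.2-fold and Msln at least 19.1-fold higher. Tgfbi was at least 16.1-fold, Sdc3 at least 10.04-fold, Selp at least 14.6-fold, Aoc3 at least 9.78-fold and Col2a1 at least 3.99-fold lower than the mean of the MSC arrays. Against the nearer MSC array these bounds were 8.21-fold, 7.16-fold, 8.78-fold, 4.83-fold and 2.28-fold. Osteoblast and osteocyte markers had a median of -0.01, with Sp7 at 8.58, Alpl at 5.33 and Bglap at 6.46 on the deposited log2 scale. Glucocorticoid targets had a median of 1.74 and cell cycle genes of -1.78. Acan, Eng, Thy1, Pou5f1, Nanog and Sox2 stayed under a log2 value of 6 on at least 7 of 8 arrays.

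**Figure D2:**
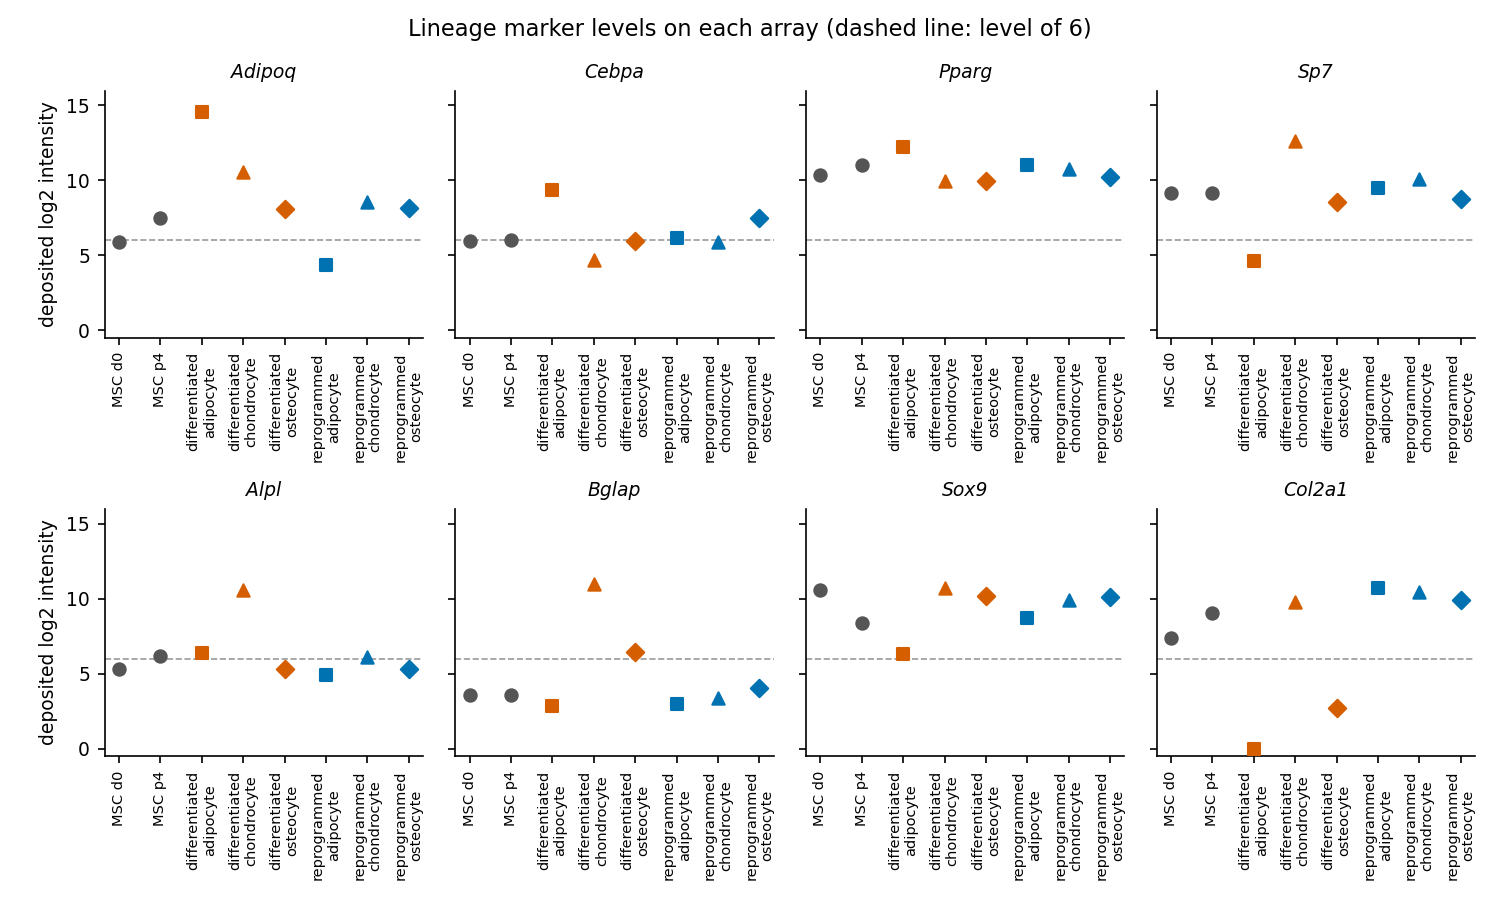
Deposited log2 values (vertical) of 8 lineage marker genes on each of the 8 arrays (horizontal), 1 point per array, with a dashed line at the level of 6. Adipoq is highest on differentiated adipocytes (14.6), and Sp7 (12.6), Alpl (10.6) and Bglap (10.98) are highest on differentiated chondrocytes. Col2a1 is highest on reprogrammed adipocytes (10.7).

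Reprogrammed cells were compared with differentiated cells, the comparison the series title names, and carried less Serpina3n and Fkbp5 and more Sprr1a. Serpina3n fell by a log2 of 6.79 (SE 0.48, adjusted p = 0.00306; 3 arrays against 3) and at least 28.6-fold, to below the level of 6 on every reprogrammed array. Fkbp5 fell by 4.18 (SE 0.25, adjusted p = 0.00184), from a log2 of 11.5 ± 0.21 to 7.36 ± 0.27 (SD, n = 3 each). Sprr1a, a small proline-rich protein, rose by 4.48 (SE 0.46, adjusted p = 0.015; at least 9.51-fold). In all 54 genes passed limma's test, 21 higher and 33 lower, of 905 higher and 971 lower at an unadjusted p under 0.05. With lineage as a block over the 6 reprogrammed and differentiated arrays limma called 7 genes, 6 of them among the 54. Without that block it called 60 on the same arrays. Arrays did not overlap at 1143 genes higher and 1343 lower, where chance gives 10% for 3 arrays against 3. Both states also lie in different array sets, so the excess does not measure the state alone.

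Genes that fell in reprogrammed cells included enzymes and receptors. Aldh1a7, an aldehyde dehydrogenase, differed by -6.26 (SE 0.67, adjusted p = 0.0188; at least 30.3-fold; -5.43 with the array set as a block) and Hsd11b1 by -5.72 (SE 0.67, adjusted p = 0.02; blocked -8.01). Vldlr differed by -4.44 (SE 0.37, adjusted p = 0.00653; at least 18.8-fold; blocked -3.02), Amy2a5 by -4.58 (adjusted p = 0.0367; at least 11.4-fold; blocked -2.76) and Map7d2 by -4.21 (adjusted p = 0.0316; at least 5.83-fold; blocked -4.02). Porcn, which acylates Wnt proteins for secretion, differed by -3.51 (adjusted p = 0.0278; blocked -2.44), Mertk by -3.50 (adjusted p = 0.0138; at least 7.21-fold; blocked -2.84) and the fibroblast growth factor receptor Fgfr2 by -3.45 (adjusted p = 0.0321; blocked -3.16). Tns1 at -2.96 (at least 3.35-fold), the Wnt target Axin2 at -2.92 (at least 2.51-fold) and Nampt, an enzyme of NAD synthesis, at -2.08 passed too.

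Genes that rose included Crabp1, which binds retinoic acid, by 3.39 (SE 0.44, adjusted p = 0.0278; at least 4.52-fold; 3.11 with the array set as a block), Esm1 by 3.13 (SE 0.51, adjusted p = 0.049; blocked 2.90) and the neurofilament gene Nefm by 2.93 (adjusted p = 0.0297; at least 3.77-fold; blocked 1.60). The mitotic spindle genes Ckap2 and Ckap2l rose by 2.75 (adjusted p = 0.0367; blocked 2.01) and 2.69 (adjusted p = 0.04997; at least 3.91-fold; blocked 1.34), and the condensin gene Ncapd2 by 2.47 (adjusted p = 0.04997; blocked 1.22). Galnt18, of protein O-glycosylation, rose by 2.57 (adjusted p = 0.02; at least 3.50-fold; blocked 2.89), Marcksl1 by 2.45 (adjusted p = 0.0433; blocked 3.29) and the adhesion gene Kirrel3 by 2.42 (adjusted p = 0.02; at least 1.58-fold; blocked 2.26). Blocked values were -6.75 for Serpina3n, -4.67 for Fkbp5 and 2.77 for Sprr1a.

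With the array set as a block limma called 0 genes (170 unadjusted). All 54 kept their sign, 48 of them at an unadjusted p under 0.05, and their median size went from 2.42 to 2.01. Leaving out the reprogrammed osteocyte, adipocyte or chondrocyte array left 2 genes each time, Fkbp5 and Serpina3n, and leaving out differentiated adipocytes gave 216, with all 54 among them. Of the 54, 24 were called without differentiated chondrocytes, 24 without differentiated osteocytes and 41 without either MSC array.

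Glucocorticoid target genes fell in reprogrammed cells, 18 of 18 being lower, with a median of -1.33 (-1.25 at the bound; camera, adjusted p = 5.86e-09). The list had an adjusted p = 0.17 with an estimated correlation, an adjusted p of 0.00255 with fry and a median of -1.41 with the array set as a block (adjusted p = 8.83e-12). Over all genes 6 passed: Fkbp5, Tsc22d3 (-3.12, adjusted p = 0.0206), Mt2 (-2.58, adjusted p = 0.0367; at least 2.84-fold), Zbtb16 (-2.30, adjusted p = 0.0367; at least 1.85-fold), Per1 (-2.02, adjusted p = 0.0278) and Klf9 (-1.36, adjusted p = 0.0375). Adjusted over the list alone 11 passed, while Lcn2 stood at -5.40 (adjusted p = 0.145; at least 12.6-fold) and Glul at -3.09 (adjusted p = 0.0769; at least 4.43-fold).

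Cell cycle genes rose, 37 of 37 being higher, with a median of 2.20 (1.99 at the bound; adjusted p = 2.28e-17). The list had an adjusted p = 0.881 with an estimated correlation, an adjusted p of 0.189 with fry and a blocked median of 0.59 (adjusted p = 0.00822). Top2a, the topoisomerase of dividing cells, stood at 3.50 (SE 0.76, adjusted p = 0.0769), Birc5 at 3.14 (adjusted p = 0.098), Kif11 at 3.11 (adjusted p = 0.0563; at least 3.94-fold) and Cenpa at 3.07 (adjusted p = 0.0998). The count was 0 over all genes and 33 adjusted over the list alone. Smooth muscle and contractile genes rose as a list, 13 of 13 being higher, with a median of 1.54 (adjusted p = 2.85e-06, and adjusted p = 0.881 with an estimated correlation; blocked 1.33, adjusted p = 6.03e-05). Their largest differences were Ankrd1 at 3.96 (adjusted p = 0.143), Tpm2 at 3.04 (adjusted p = 0.0901), Myl9 at 2.57 (adjusted p = 0.119) and Acta2 at 2.32 (adjusted p = 0.211). Of them 7 passed adjusted over the list alone.

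Fibrillar collagen and matrix genes rose by a median of 0.91 (20 of 25 higher, adjusted p = 0.0199, and adjusted p = 0.987 with an estimated correlation; blocked 1.24, adjusted p = 6.03e-05), with Tnc at 3.01, Col1a1 at 2.16, Fstl1 at 2.04 and Timp1 at 2.04 and 1 member passing adjusted over the list alone. Adipocyte markers fell by a median of -1.62 (-0.89 at the bound; 19 of 20 lower, adjusted p = 0.0324, and adjusted p = 0.987 with an estimated correlation; blocked -1.63, adjusted p = 0.00443), with Cidec at -4.30 (at least 6.13-fold), Adipoq at -3.75, Pnpla2 at -3.02 and Lpin1 at -2.38 and 0 passing adjusted over the list alone. Without differentiated adipocytes the medians were 0.13 (adjusted p = 0.756) and -0.12 (adjusted p = 0.57). The matrix call was also lost without reprogrammed osteocytes (0.87, adjusted p = 0.186) and the adipocyte call without reprogrammed chondrocytes (-1.58, adjusted p = 0.0555). With the array set as a block interferon response genes passed as well, at 2.76 (adjusted p = 1.53e-15) against 0.03 (adjusted p = 0.853) without it, as did mitochondrial respiratory chain genes (-0.23, adjusted p = 0.0336; -0.16 without it) and hypoxia and glycolysis genes (-0.47, adjusted p = 0.0336; 0.19 without it). These 3 lists had an adjusted p = 0.912 with an estimated correlation and that block. The block takes off the difference between MSC p4 and MSC d0, 1 array each. Relative to the mean of both, interferon genes stood at -1.48 on MSC p4 and 1.48 on MSC d0. Their blocked value therefore largely restates the difference between the MSC arrays.

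No other list passed. DNA and histone methylation enzymes had a median of 0.37 (adjusted p = 0.0768), with Uhrf1 at 2.64, Ezh2 at 1.76 and Dnmt1 at 1.48 and 4 members passing adjusted over the list alone, and mesenchymal transition regulators 0.76 (adjusted p = 0.124), with Vim at 1.93, Zeb1 at -1.32 and Snai2 at 1.19. The remaining adjusted p lay between 0.306 and 0.975. Medians were 0.27 for MSC surface and stromal markers, 0.14 for pluripotency genes, -0.21 for CDK inhibitors and senescence genes, -0.73 for macrophage and monocyte markers, 0.64 for inflammatory genes, 0.33 for cholesterol synthesis genes, -0.08 for BMP, TGF-beta and Wnt targets, 0.06 for ribosomal protein genes and 0.21 for imprinted growth genes. Median, mean and test differed in sign for osteoblast and osteocyte markers (median 0.45, mean -0.16), chondrocyte markers (median 0.23, test downward), osteoclast markers (median -0.31, test upward) and stress genes (median 0.03, mean -0.05). Of 25 pluripotency genes with a probe only 5 were tested, without Pou5f1, Nanog and Sox2, so their median says little of that list. Of chondrocyte, macrophage and osteoclast markers with a probe, 7 of 35, 3 of 26 and 3 of 12 were tested. Cdkn1a differed by -1.40 (adjusted p = 0.0563), Cdkn2a by 0.63 (adjusted p = 0.475), Cd44 by 1.73 (adjusted p = 0.169), Col2a1 by 4.25 (adjusted p = 0.134), Klf4 by 0.82 (adjusted p = 0.501), Alpl by -1.76 (adjusted p = 0.371), Bglap by -2.63 (adjusted p = 0.295; at least 2.12-fold), Sp7 by 0.62, Sox9 by 0.45, Myc by 0.14, Cebpa by -0.26 and Pparg by -0.06. Egfl7 was the 1 endothelial and Hp the 1 lymphoid or granulocyte marker tested, and 0 erythroid markers were.

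**Figure D3:**
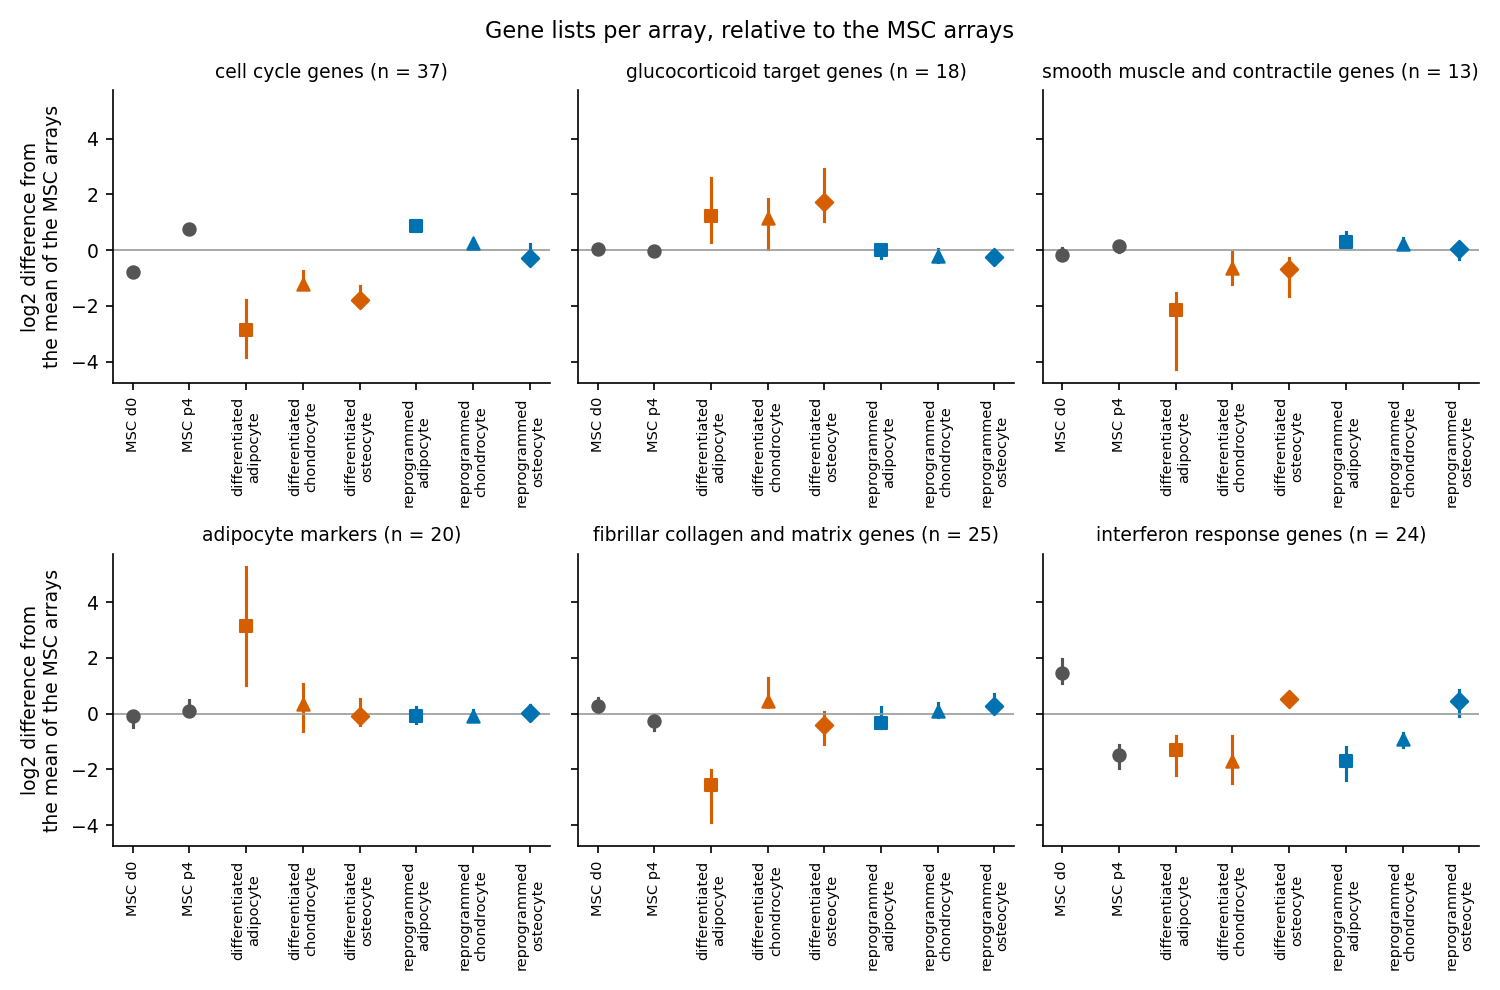
Log2 difference from the mean of both MSC arrays (vertical) for 6 gene lists, 1 point per array at the list's median with a bar over the quartiles of its genes. Glucocorticoid targets lie above MSCs on each differentiated array (1.23, 1.16 and 1.74 for adipocytes, chondrocytes and osteocytes), and cell cycle genes below (-2.88, -1.20 and -1.78).

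Each reprogrammed array was also set against the differentiated array of its lineage, 1 array against 1. Adipocytes differed at 1414 genes higher and 1487 lower, chondrocytes at 717 and 963, and osteocytes at 680 and 962. In adipocytes Adipoq was at least 301.9-fold, Lcn2 at least 373.9-fold, Ces1d at least 183.3-fold, Cidec at least 189.9-fold and Sult1a1 at least 122.9-fold lower after reprogramming, and Ankrd1 was at least 62.9-fold, Col2a1 at least 20.9-fold, Prkg2 at least 19.3-fold, Cemip at least 14.05-fold and Pclaf at least 22.7-fold higher. Adipocyte markers had a median of -3.38 (-2.77 at the bound). Of 35 with a probe 25 reached the filter's level on the differentiated and 15 on the reprogrammed adipocyte array. The choice by level can therefore enlarge this fall. In chondrocytes Bglap2 was at least 62.9-fold, C1qtnf3 at least 46.7-fold, Ptgis at least 34.7-fold, Bglap at least 25.4-fold and Serpina3n at least 21.05-fold lower, and Dlk1, an inhibitor of fat cell formation, was at least 39.8-fold, Sprr1a at least 12.9-fold and Osr2 at least 7.23-fold higher, with Itih2 at 4.28 and Esm1 at 4.06. Osteoblast markers had a median of -1.35 and chondrocyte markers of -1.31 there, beside macrophage markers at -2.30 (-1.002 at the bound). On the differentiated chondrocyte array 20 of 31 osteoblast, 13 of 35 chondrocyte and 9 of 26 macrophage markers reached the filter's level. On the reprogrammed one 14, 7 and 2 did. Members that entered through the differentiated array can enlarge these falls. Over all markers with a probe, median deposited log2 levels were 8.56, 5.08 and 5.38 on the differentiated array. They were 5.29, 3.40 and 3.82 on the reprogrammed one. In osteocytes Serpina3n was at least 65.9-fold, Aldh1a7 at least 78.0-fold, Cldn11 at least 40.2-fold, Sult1a1 at least 62.4-fold and Aldh1a1 at least 36.1-fold lower, and Col2a1 was at least 12.2-fold, Tgfbi at least 8.11-fold, Tnc at least 15.7-fold, Crabp1 at least 8.60-fold and Selp at least 13.1-fold higher. Cell cycle genes had medians of 3.89, 1.43 and 1.45 and glucocorticoid targets of -1.59, -1.27 and -1.95 in adipocytes, chondrocytes and osteocytes.

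Reprogrammed cells were set against MSCs, and no gene passed. Limma called 0 genes, against 10 higher and 17 lower at an unadjusted p under 0.05, and 0 with the array set as a block (18 unadjusted) or with the MSC and reprogrammed arrays alone (88 unadjusted). Among genes at an unadjusted p under 0.05, the largest differences without overlap of arrays were Nefm at 2.25 (SE 0.44; blocked 1.58), Sprr1a at 1.61 (SE 0.51; blocked 0.76) and Crabp1 at 1.23 (SE 0.49; blocked 1.09) on the higher side. On the lower side they were Stc1, a secreted glycoprotein hormone, at -1.75 (SE 0.75; blocked -1.18) and Egr2 at -1.31 (SE 0.55; blocked -1.16). Zcchc3 at -1.24 (SE 0.38, blocked -1.13) and the chemokine Ccl7 at -1.23 (SE 0.37; blocked -1.45) came next, over 3 arrays against 2. Bcl6b (0.93, at least 1.19-fold), Hspbp1 (0.86), Tuba3a (0.79), Khsrp (0.75), Rad23b (0.74) and Patz1 (0.58, at least 1.24-fold) followed, and St3gal1 (-0.93, at least 1.36-fold), Rgs16 (-0.92), Il7 (-0.87), Pkia (-0.83), Kbtbd4 (-0.82) and Hectd3 (-0.77). The level of Zcchc3 allows no fold. Marker genes differed by 2.06 (SE 1.54) for Col2a1, 0.63 for Cdkn2a, 0.45 for Cd44, 0.43 for Adipoq, 0.16 for Klf4 and -0.30 for Cdkn1a. A p that misses the threshold does not show that the states did not differ, and the spread here included the wide difference between the MSC arrays.

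Of the gene lists, 5 passed camera in this comparison and none did with an estimated correlation or with fry. No member of them passed over all genes or adjusted over the list alone. Cholesterol synthesis genes rose by a median of 0.31 (16 of 17 higher, adjusted p = 0.000264, and adjusted p = 0.983 with an estimated correlation), with Fdps at 0.61, Mvd at 0.59 and Dhcr7 at 0.57. Their median was 0.10 (adjusted p = 0.56) with the array set as a block or without MSC d0. Inflammatory genes fell by a median of -0.70 (7 of 9 lower, adjusted p = 0.0177, and adjusted p = 0.688 with an estimated correlation; blocked -0.71, adjusted p = 0.00095), with Il1rn at -1.34 and Cxcl1 at -1.24. Without MSC p4 it was -0.16 (adjusted p = 0.615) and without reprogrammed chondrocytes -0.55 (adjusted p = 0.092).

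The other 3 lists turned sign with the array set as a block or without MSC d0, which gave the same values. Cell cycle genes had a median of 0.30 (34 of 37 higher, adjusted p = 0.00038, and adjusted p = 0.983 with an estimated correlation), and -0.43 (adjusted p = 0.000285, and adjusted p = 0.945 with an estimated correlation) with the block, with Rrm2 at 0.93, Mcm7 at 0.86 and Mcm3 at 0.72. Interferon response genes had a median of -0.74 (-0.66 at the bound; 24 of 24 lower, adjusted p = 0.00176, and adjusted p = 0.983 with an estimated correlation), and 0.75 (adjusted p = 5.34e-05, and adjusted p = 0.945 with an estimated correlation) with the block, with Ifi27l2a at -2.05, Oas2 at -1.70 (at least 1.27-fold) and Rsad2 at -1.69. Hypoxia and glycolysis genes had a median of 0.32 (16 of 22 higher, adjusted p = 0.0177, and adjusted p = 0.983 with an estimated correlation), and -0.06 (adjusted p = 0.778) with the block, with the glycolytic enzymes Pgam1 at 1.03, Aldoa at 0.87 and Pgk1 at 0.84. Without reprogrammed adipocytes the medians were 0.04 (adjusted p = 0.457), -0.19 (adjusted p = 0.559) and 0.25 (adjusted p = 0.0844), and interferon genes stood at -0.60 (adjusted p = 0.092) without reprogrammed chondrocytes. Glucocorticoid targets had a median of -0.21 (adjusted p = 0.143), contractile genes 0.22 (adjusted p = 0.0565), macrophage markers -0.56 (adjusted p = 0.0565) and imprinted growth genes 0.24 (adjusted p = 0.163; 0.51, adjusted p = 0.0386, with the block, and adjusted p = 0.945 with an estimated correlation and the block), and all others had adjusted p from 0.572 to 0.948. Median and test differed in sign for MSC surface markers (-0.01), adipocyte markers (-0.03), pluripotency genes (-0.03), senescence genes (-0.04), mitochondrial genes (-0.01) and ribosomal protein genes (-0.0048). Here too only 5 pluripotency genes and 3 macrophage markers were tested.

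Against both MSC arrays, reprogrammed adipocytes had 13 genes at least 2-fold higher and 78 lower, reprogrammed chondrocytes 10 and 1, and reprogrammed osteocytes 75 and 39. These totals of 91, 11 and 114 were 1567, 580 and 660 against MSC d0 alone, and against MSC p4 alone they were 151 for chondrocytes and 865 for osteocytes. Nefm was higher by 1.99 in adipocytes and 1.56 in chondrocytes, Dpep1 by 1.98 in chondrocytes and 2.01 in osteocytes, and Dlk1 by 1.60 in chondrocytes and 1.85 in osteocytes. Reprogrammed adipocytes had Col2a1 higher by 1.59, and Tmem176a by at least 2.46-fold, Il11 by at least 1.93-fold and Igsf5 by at least 1.25-fold. They had the peroxidase Gpx3 lower by at least 20.9-fold, Bmp4 by at least 5.67-fold, Agt by at least 4.81-fold, Stc1 by at least 4.20-fold against the mean of the MSC arrays, and Mmp13 at -2.53. Against the nearer MSC array the bounds of Gpx3, Bmp4, Agt and Stc1 were 18.3-fold, 3.93-fold, 2.799-fold and 2.83-fold. The pentraxin Ptx3 was lower in chondrocytes (-1.56) and osteocytes (-1.78). Reprogrammed chondrocytes also had Tnc at 1.43 and Ier2 at least 1.71-fold higher, and osteocytes Creb3l1 at 2.03, Crabp1 at 2.02 and Gsk3a at least 2.83-fold higher, with Npepl1 at -1.48 and Rpap3 at -1.47. A limma fit over 7 cell types, with the spread taken from the MSC arrays, called 0 genes in each of the 9 single-array comparisons with a differentiated or reprogrammed array (unadjusted 579 to 1708 for differentiated cells and 11 to 111 for reprogrammed cells against MSCs, and 600 to 1605 between them).

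How much of a differentiation difference was left after reprogramming was measured across 8317 genes as the slope of the reprogrammed difference from MSC p4 on the differentiated difference from MSC d0. The slope was 0.010 for adipocytes, -0.059 for chondrocytes and -0.007 for osteocytes. Of 2297, 1242 and 818 genes that differed at least 2-fold in the differentiated cells, 57 (2.48%), 35 (2.82%) and 107 (13.1%) still did in the same direction, and 34, 65 and 106 in the opposite direction. Each lineage's deviation from the other lineages correlated between its differentiated and reprogrammed arrays at r = 0.169 for adipocytes, 0.087 for chondrocytes and 0.228 for osteocytes. The mean was 0.161, against -0.079 for mismatched lineages and at most 0.048 for the other pairings of all 6. Deviations of the lineages cancel out within each state by construction. A positive matched mean therefore brings a negative mismatched mean with it, and the contrast between them is no separate evidence. An exact one-sided test over these 6 pairings gave p = 0.167, the smallest it can give.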

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

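All tests in this part were chosen after the values had been seen, as were the limits for listing a result, and the differences between lineages listed here rest on 1 array each and were not tested. Bootstrap intervals resample genes and measure no spread between arrays or cultures. Of 48 comparisons of a list between lineages, 8 had lineages on opposite sides of random lists, beyond the 99th percentile in 1 and below the 1st in another with a median of at least 0.5 each way; looser limits gave 10, and opposite signs alone 34.

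Osteoblast and osteocyte markers had medians against MSCs of 1.31 in differentiated chondrocytes and -0.64 in differentiated adipocytes, a gap of 1.96. For reprogrammed minus differentiated cells of the same lineage the medians were 0.56 in adipocytes and -1.35 in chondrocytes, a gap of 1.90. Such a gap can carry the differentiated gap with its sign turned and is no gap between reprogrammed cells. Markers that entered through the differentiated chondrocyte array can also enlarge both osteoblast gaps. Fibrillar collagen and matrix genes had a gap of 3.16 between differentiated chondrocytes (0.71) and adipocytes (-2.45). For reprogrammed minus differentiated cells it was 2.90 (2.07 in adipocytes, -0.83 in chondrocytes). On the reprogrammed arrays their medians relative to the mean of both MSC arrays were -0.33 in adipocytes and 0.10 in chondrocytes, over 25 genes. Interferon response genes had a gap of 2.19 between differentiated osteocytes (0.52) and chondrocytes (-1.68). Hypoxia and glycolysis genes had a gap of 1.51 for reprogrammed minus differentiated cells, between adipocytes (0.88) and chondrocytes (-0.64). BMP, TGF-beta and Wnt target genes had a gap of 2.22 between differentiated chondrocytes (1.14) and adipocytes (-1.08). Imprinted growth genes had a gap of 1.96 between differentiated osteocytes (0.66) and adipocytes (-1.30).

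Osteoblast markers such as Sp7, Alpl and Bglap were highest on the array labelled chondrocyte, not on the one labelled osteocyte. An exchange of these labels would place chondrocyte markers on the array labelled osteocyte. Over all 35 of them, with no choice by level, their median was instead higher by 0.40 (bootstrap interval 0.21 to 1.01) on the array labelled chondrocyte, in 27 genes. This direction is opposite to an exchange. It rests on 1 array against 1, and only 14 of the 35 reached the level of 6 on any array, so it does not decide. The 14 at the level of 6 on any array gave 1.46, a size that choosing by level can raise, and the 7 at that level on any of the other 6 arrays gave 1.08 (-0.47 to 1.53), too few to decide. On the array labelled chondrocyte 9 of 26 macrophage markers reached the level of 6 (at most 3 on any other array); Lyz1 (9.19), Laptm5 (8.14), Clec4d (7.22) and Ctss (7.17) were among the 9, while Cd74 (3.49), Tyrobp (3.48), Ptprc (4.39) and C1qa (2.10) stayed under it. Bone-like change within the chondrocyte culture over its time in culture may be a source and was not tested.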

How the results depend on the processing

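The alternatives on the offset, on levels of 5 and 7, on the array set as a block for comparisons with MSCs and for lists in all comparisons, on lists with 1 array left out and on level at 2 arrays in single-array counts were chosen after seeing the data. The planned background corrections (negative controls, an offset of 50 after normexp, none), scaling to a common median and filters on detection p were not run, because the table they need was not used here. Among single genes 685 values kept their direction and side of the threshold, 455 kept the direction without passing and 0 turned; among lists 218, 82 and 11 did; of the other values 127 stayed within the limits for a like value and 84 moved. Except where the setting itself shows it (fewer arrays or genes), the cause was not tested. Dim genes are limited by the floor of the values.

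The count of 54 genes between reprogrammed and differentiated cells was 29 with the level of 6 on all 8 arrays, 0 with the array set as a block and 2 to 216 with 1 array left out. With lineage as a block it was 7, 6 of them among the 54. Matched lineages correlated in their deviations at r = 0.169, 0.087 and 0.228, and their mean r was above that of every other pairing. The labels name no culture or animal shared by arrays of 1 lineage, and the main fit was designed without this block.

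The count of 5 genes between differentiated cells and MSCs was 9 with an offset of 50, 2 with no offset, 3 with no filter, 1 with the level on all 8 arrays, 9 at a level of 7, 11 with trend and robust moderation, 1 with the array set as a block, 0 with the MSC and differentiated arrays only (limma, 509 unadjusted), and 1 to 56 with 1 array left out.

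Camera with an estimated correlation called 0 lists in each of the 3 comparisons, with or without the array set as a block, and fry called 1 for reprogrammed against differentiated cells, 1 for differentiated cells against MSCs and 0 for reprogrammed cells against MSCs. With 1 array left out the lists called ranged from 4 to 9 for differentiated cells against MSCs, 4 to 7 for reprogrammed against differentiated cells and 3 to 7 for reprogrammed cells against MSCs. The last were 3 with no filter and 3 with the level on all 8 arrays, and reprogrammed against differentiated cells had 8 with the array set as a block. Medians that turned with 1 array left out ranged from -2.21 to 0.69 for interferon response genes and from -1.49 to 0.0012 for matrix genes in differentiated cells. In reprogrammed cells against MSCs they ranged from -0.43 to 1.05 for cell cycle genes, -2.16 to 0.75 for interferon response genes and -0.0626 to 0.57 for hypoxia genes, and with the array set as a block they were -0.43, 0.75 and -0.0626.

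Single-array counts of 2-fold genes are given in the order adipocytes, chondrocytes, osteocytes. With the level on all 8 arrays they were 956, 336 and 245 for differentiated cells against MSCs, 47, 1 and 57 for reprogrammed cells against MSCs, 1767, 835 and 932 between them, and 675 between the MSC arrays. At a log2 difference of 1.5 they were 979, 453 and 284, then 25, 4 and 15, then 1668, 815 and 668, and 494. Against MSC d0 alone differentiated chondrocytes had 1429, and reprogrammed cells 1567, 580 and 660. Against MSC p4 alone differentiated cells had 2754, 1991 and 1966, reprogrammed chondrocytes 151 and reprogrammed osteocytes 865. With an offset of 50 reprogrammed adipocytes had 53 and osteocytes 54, with no offset 137 and 172, and with no filter reprogrammed chondrocytes had 20. Limma over 7 cell types gave 0 in all 9.

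The slope for osteocytes was -0.0597 with the level on all 8 arrays. With the MSC arrays exchanged the slopes were -0.258, -0.237 and -0.226, since the exchange puts the MSC difference into both sides with opposite sign by construction.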

Other observations

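All tests in this part, and their limits, were chosen after the results had been seen. Bootstrap intervals resample genes and measure no spread between arrays or cultures. Dlk1, an imprinted gene whose product holds back fat cell formation, differed by 4.799 between reprogrammed and differentiated cells (SE 0.95; 6.61 with the array set as a block; limma's adjusted p = 0.0714; 3 arrays against 3). Its log2 level was 11.9, 10.5 and 11.6 on reprogrammed osteocytes, adipocytes and chondrocytes, 8.73, 5.81 and 5.09 on the differentiated ones, and 10.04 and 8.23 on MSC d0 and MSC p4. The median of 24 interferon response genes, as a log2 difference from the mean of both MSC arrays, was 1.48 on MSC d0 and -1.48 on MSC p4. It was -1.30, -1.70 and 0.53 on differentiated adipocytes, chondrocytes and osteocytes, and -1.69, -0.90 and 0.45 on the reprogrammed ones. Ifit3 stood at 13.9 on MSC d0 and 8.44 on MSC p4, at 7.37, 7.89 and 11.9 on differentiated adipocytes, chondrocytes and osteocytes, and at 7.37, 9.99 and 12.7 on the reprogrammed ones.

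The MSC arrays differed at least 2-fold at 1248 genes, and if the array set were the cause, reprogrammed arrays would lie at MSC p4 on the line from MSC d0 (0) to MSC p4 (1). Their mean position was 0.71 (0.41 to 1.02, mean minus and plus 1 SD), with 1.04 for adipocytes, 0.67 for chondrocytes and 0.43 for osteocytes. Differentiated adipocytes and chondrocytes, in the set of MSC d0, lay at 0.34 and 0.37, and differentiated osteocytes at 0.03. With 1 array per cell type, set, lineage and culture cannot be told apart. Macrophages on MSC d0 would have to hold at least 50% of its RNA to leave genes 2-fold higher on MSC p4, but the median log2 level of 26 markers there was 3.81 (bootstrap interval 3.49 to 4.70), which argues against them for those genes. For genes lower on MSC p4 they cannot be told apart, since only 3 of 26 markers (Lyz1, Lyz2 and Cd14) reached the level of 6 on either array, and the median difference between the arrays was 0.26 (-0.20 to 0.62). A difference in passage or time in culture may lie behind the pattern and was not tested.

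Glucocorticoid target genes such as Fkbp5, Tsc22d3 and Per1 were higher on all 3 differentiated arrays. The array set as the cause would separate the MSC arrays at these genes, and their median difference was -0.0736 (-0.18 to 0.25), which argues against it. A candidate explanation is a glucocorticoid in the differentiation media, which the labels used here do not describe, and it was not tested. A response of differentiated cells to their own hormone environment stays open as untested too.

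Of the 10 splits of the 6 reprogrammed and differentiated arrays into 3 and 3, 1, the real one, gave as many genes as 54, and the highest count of the others was 0. The splits are too few for a share under 0.05. The real split also divides the arrays by array set, and every other split mixes both states and both sets. The counts therefore do not tell a difference of state from a difference of set.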
